A study of Mus musculus with 6 samples.

How the data were processed

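The labels describe the samples as primary cortical neurons from embryonic day 14.5 C57BL/6 mouse brain. Per their protocols, single cells were profiled with droplet libraries (10x Genomics Chromium) read on an Illumina NovaSeq. Most cells analysed here carried no neuronal class. The 6 labelled samples form 2 groups, 3 control samples under 21% oxygen and 5% carbon dioxide and 3 samples given 3% sevoflurane in the same gas for 2 h a day on 3 days. The labels do not say whether samples of a group came from separate litters or cultures. The extraction protocol in the labels describes total RNA from Trizol with a quality check, followed by the droplet libraries, and does not say how a cell suspension was made.

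The authors deposited 1 table of natural log values for 20706 genes in 30648 cells, and per the submitters' processing notes CASAVA 1.8, Cell Ranger and Seurat were used with the mm10 build. Versions of the last 2 tools, the gene annotation and any filter on cells are not given in the sources used here. On the values themselves, the exponential minus 1 summed to 10000 in every cell, so each value is the natural log of 1 plus the unique molecular identifiers (UMIs) of a gene per 10000 UMIs of that cell. Every value above 0 was a whole multiple of its cell's smallest value within a tolerance of 0.001, which gave back the UMIs of each gene and the depth of each cell. The cells held between 201 and 5133 detected genes. Values above 0 made up the smaller part of the table, with 87.7% of entries at 0.

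Each cell name ends in a number from 1 to 6, which is taken here as the library. Pairs of these libraries shared between 26 and 43 barcode sequences. The descriptions of the samples are numbered from 1 to 6 as well, with the 3 controls first, but no label says that these are the library numbers, and neither the numbers nor their order were used as a key. So all 30648 columns stayed without a sample and no library was placed in the control or the sevoflurane group. The comparisons of sevoflurane with control that were planned before the data were examined were therefore not made. These were limma tests over all cells and within classes, permutation tests of shares and depth, and set tests of gene lists. Levels are given as the median of the 6 libraries with their range, or as each library's value. No p-value is given, and a range over libraries of unknown group can hold an effect of exposure as well as the spread between samples.

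Cells were clustered in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. The 2000 genes with the highest dispersion for their mean were used, after 481 genes of the fixed lists that were not cell type markers had been left out, so that clusters were not drawn from the genes described within them. A principal component analysis gave 30 components of the scaled values. A graph of the 20 nearest neighbours with Jaccard weights was partitioned by the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Doublets were scored in each library against simulated sums of cell pairs, with the threshold from scikit-image 0.26.0. Between 0.800% and 2.22% of the cells of a library were called doublets, and between 35.7% and 49.9% of the simulated ones passed the same threshold. Called doublets were kept in the main result and left out in an alternative.

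Clusters were called X-like from marker sets fixed before the data were examined. The scoring rule was set, and then changed in 2 further versions, after the leading genes of the clusters had been seen. In its final form a marker counted when its mean was at least 0.1 UMIs per 10000 and at least 2 times that of the other cells. A cluster took the class with the largest share of its markers counted, given at least 3 markers and 40% of the set. It stayed unnamed when an unrelated class also had 4 markers and 50% of its set, when its depth was low without a leading marker, or when leading genes went against the name. The last clause left 1495 dividing cells led by Helt, Insm1 and Gsx2 unnamed, which an earlier version had called intermediate progenitors, and the 40% minimum left out 68 cells led by the neutrophil genes S100a8 and S100a9. Another 3 unnamed clusters, of 139, 104 and 103 cells, carried microglial genes together with neuronal or glial ones. No cluster took the intermediate progenitor name. Bcl11b, a marker of the excitatory set, was not analysed here.

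Levels of a gene in a class are means over cells of UMIs per 10000, computed in each library for the 9 classes with at least 50 cells in every library. The other 3 classes are given as UMIs pooled over libraries with exact Poisson 95% intervals, and single shares carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only. Of the 25 gene lists fixed beforehand, 24 were analysed. They were the lists of immediate early genes, apoptosis and p53, endoplasmic reticulum and integrated stress, heat shock, antioxidant response, nuclear oxidative phosphorylation, glycolysis and hypoxia, cytosolic ribosomal proteins, GABA and glycine receptors, glutamate receptors, potassium channels, presynaptic release, postsynaptic density, neurotrophins and plasticity, axon growth, tau and amyloid processing, inflammatory signalling, interferon response, S phase, G2 and M phase, sterol synthesis, autophagy and lysosome, iron handling, and blood and serum. The 13 mitochondrially encoded transcripts were not analysed here. A member was described by class when it was no cell type marker and reached 0.1 UMIs per 10000 in the class where its median was highest.

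The planned rule for named genes ranked them by p-value and could not be applied. In its place, chosen after the data were examined, each list gives up to 4 members with the largest ratio of the highest class to the next. Over all cells, the genes named are those with the largest ratio of the highest library to the lowest, among 9378 genes with a mean of at least 0.1, UMIs in at least 100 cells of every library and more than a systematic name. Other genes were chosen after their values were seen, and some genes that these rules would name are not reported here. Distances between libraries are root mean squares of log2 differences with a pseudocount of 0.01 UMIs per 10000. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 names.

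The recovery of UMIs was tested on simulated data: in 500 simulated cells and 20706 genes, 100% of 1461290 values came back. For the spread between the 6 libraries, 200 of 9721 genes were raised 1.5-fold in a library drawn at random, and 100% showed a ratio of at least 1.375, against 0.0105% of the unchanged genes. This simulation holds counting noise only. Alternatives were other clustering resolutions, doublets left out, cells with at least 1000 detected genes, UMIs summed per library, equal weights for classes, centring on the median gene, other filters and pseudocounts, leaving out each library, and, added after the data were examined, clustering with the list genes, cell cycle lists without the dividing clusters, and thinning each cell to 2000 UMIs. Figures were drawn with matplotlib 3.10.9.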

Results

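The data describe 30648 single cells from 6 samples labelled as mouse primary cortical neurons, 3 of them exposed to the inhaled anaesthetic sevoflurane and 3 controls. The cells came as 6 numbered libraries that no label ties to an exposure, so the comparison of the exposures was not made, and each library is a single measurement. Libraries 1 to 6 held 5540, 5728, 4249, 4961, 5433 and 4737 cells. Their total depth lay between 27865167 and 36966829 UMIs. Median depth per cell ranged from 5434 to 6001 UMIs, and median detected genes from 2472 to 2628.

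The question open to these data is which cells the samples held and in which of them receptor, stress and other fixed gene lists were expressed. Glial classes made up the largest part. Oligodendrocyte precursor or oligodendrocyte-like cells were 22.9% of a library in the median of 6 (range 22.2% to 26.1%), and astrocyte-like cells 21.0% (17.8% to 23.2%). The 3 neuronal classes together were 19.5% (17.2% to 20.8%), which counts 1123 dividing cells of the inhibitory class. Microglia or macrophage-like cells followed with 9.03% (7.95% to 11.4%), mural or pericyte-like cells with 5.50% (3.41% to 7.35%), radial glia or progenitor-like cells with 4.57% (4.07% to 6.07%), endothelial-like cells with 4.18% (3.65% to 5.29%) and erythroid-like cells with 3.42% (2.63% to 4.29%). Fibroblast or meningeal-like cells were 1.31% (0.848% to 2.34%) and ependymal-like cells 0.953% (0.697% to 1.16%). Unnamed clusters held 6.60% (5.91% to 7.01%). The highest oligodendrocyte-lineage share, in library 1, had an exact interval of 25.0% to 27.3%, and the lowest, in library 5, one of 21.1% to 23.4%. The radial glia name was lost at resolution 2 and when the list genes entered the clustering.

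**Figure D1:**
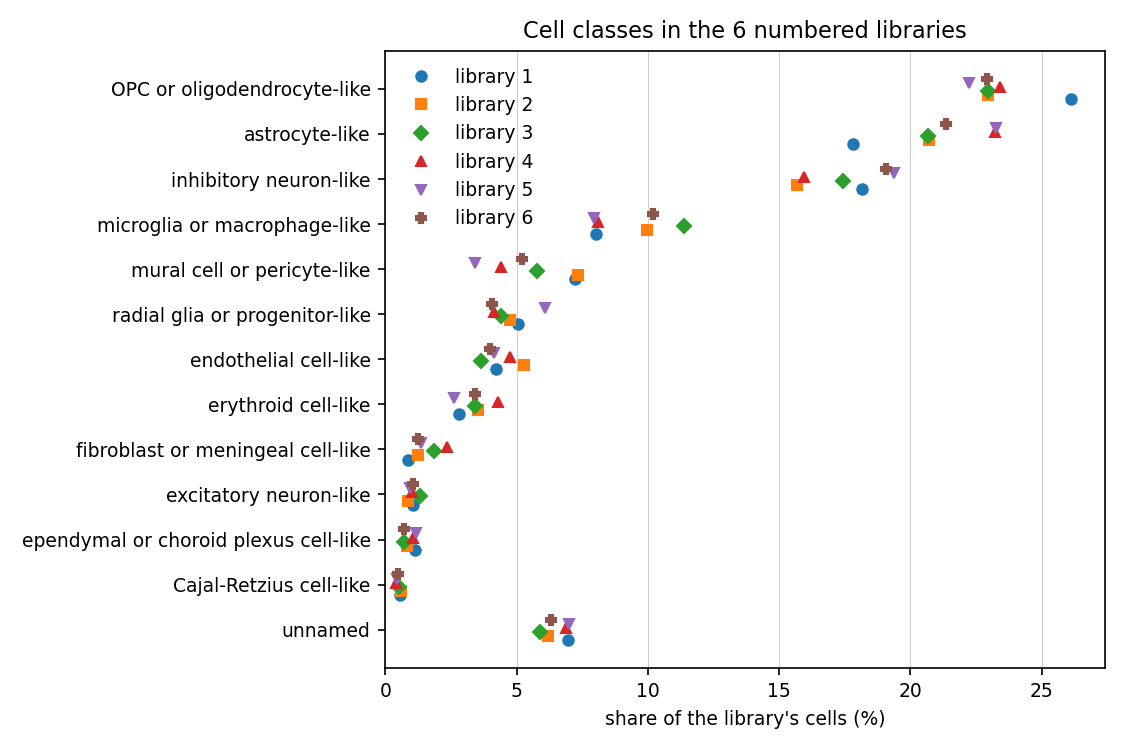
Share of each library's cells, in percent, in each cell class (OPC, oligodendrocyte precursor cell). Each symbol is 1 of the 6 numbered libraries, and oligodendrocyte-lineage cells had the highest share in 5 of 6 libraries, while excitatory neuron-like cells lay between 0.873% and 1.32%.

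Among neurons, the inhibitory class predominated. Inhibitory neuron-like cells were 17.8% of a library (15.7% to 19.4%), against 1.04% (0.873% to 1.32%) for excitatory neuron-like and 0.513% (0.423% to 0.611%) for Cajal-Retzius-like cells. The inhibitory class carried the forebrain interneuron regulator Dlx1 at 9.43 UMIs per 10000 (8.47 to 10.4), and Gad2, an enzyme of GABA synthesis, at 4.51 (4.11 to 4.92). Lhx6 and Sst, markers of interneurons from the medial ganglionic eminence, had medians of 0.00891 and 0.00495. One of its clusters, with 1123 cells, also carried 6 markers of dividing cells, and that cluster held 20.9% of the class (17.4% to 25.7%). Excitatory neuron-like cells had Tbr1 at 5.13 (4.14 to 5.87), Neurod6 at 4.76 (4.03 to 5.93) and the vesicular glutamate transporter Slc17a6 at 1.65 (1.53 to 2.28), while Slc17a7, the transporter of mature cortical neurons, gave 1 UMI in the 316 cells. The 159 Cajal-Retzius-like cells held Reln, the secreted protein of this cell type, at 39.9 UMIs per 10000 (Poisson interval 39.0 to 40.7).

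Some non-neuronal classes are described here by the leading genes of their clusters or by fixed markers. Of the oligodendrocyte lineage, 3420 cells fell in a cluster led by Resp18 and the precursor receptor Pdgfra, 473 in a cluster led by Bmp4 and Gpr17, which mark committed precursors, and 515 in a cluster led by the myelin gene Mbp. Microglia or macrophage-like cells included 1766 led by the microglial receptor P2ry12, 405 led by Spp1 and Gpnmb, and 163 led by Pf4, Lyve1 and Mrc1, genes of border macrophages. Erythroid-like cells carried Hbb-bs at 4153 UMIs per 10000 (3974 to 4321) and Alas2, the first enzyme of haem synthesis in red cells, at 15.04 (13.2 to 16.8). The 291 ependymal-like cells held the cilium gene Ccdc153 at 24.6 (Poisson interval 24.1 to 25.2), and the 447 fibroblast-like cells held Dcn at 40.1 (39.5 to 40.7).

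Ranks of list genes are by the median of 6 libraries, among the 9 classes with values per library. The top class was not always the same in 6 of 6 libraries. Of the genes highest in excitatory neuron-like cells (50 to 58 cells per library) it was for 5 of 9 presynaptic, 2 of 6 tau and amyloid and 1 of 4 heat shock genes. For sterol genes in astrocyte-like cells it was for 15 of 16, and for ribosomal genes in microglia-like cells for 37 of 45. For potassium channel genes in the oligodendrocyte lineage it was for 3 of 6. In inhibitory neuron-like cells it was for 7 of 12 axon growth, 7 of 11 S phase and 9 of 12 G2 and M phase genes. It was for 3 of 9 S phase genes in microglia-like cells. Of neurotrophin and plasticity genes it was for 1 of 3 in astrocyte-like and 1 of 3 in excitatory neuron-like cells. Of 425 list genes, 123 were higher still in the mean over the cells of at least 1 of the 3 pooled classes. Among them were 15 of 18 presynaptic, 10 of 17 antioxidant, 12 of 22 glycolysis and hypoxia, 17 of 38 oxidative phosphorylation and 7 of 14 heat shock genes. So were 9 of 20 autophagy and lysosome, 8 of 18 endoplasmic reticulum and integrated stress, 8 of 22 tau and amyloid and 6 of 14 postsynaptic genes. The count was 2 of 12 for GABA and glycine receptors, 2 of 13 for glutamate receptors and 1 of 12 for iron handling. GABA-gated receptors are a known target of volatile anaesthetics, but the list also holds metabotropic and glycine receptor subunits and the scaffold gene Gphn. Of 18 GABA and glycine and 19 glutamate list genes, 12 and 13 reached 0.1 UMIs per 10000 in some class. Most of these were highest in glial classes. Of 12 GABA and glycine receptor genes at the floor of 0.1 UMIs per 10000, 4 were highest in oligodendrocyte-lineage cells, 4 in astrocyte-like cells, 2 in radial glia-like and 2 in excitatory neuron-like cells. The glycine receptor subunit Glrb was at 1.12 UMIs per 10000 in the oligodendrocyte lineage (1.04 to 1.17) and 0.431 in excitatory neuron-like cells, but at 1.53 (Poisson interval 1.37 to 1.70) in the pooled Cajal-Retzius-like cells. Gabbr2, a subunit of the metabotropic GABA receptor, was at 1.00 in astrocyte-like cells (0.903 to 1.09). Gabra3 (chromosome X, 72432681 to 72656848, minus strand) was at 0.262 in the oligodendrocyte lineage (0.207 to 0.331) and 0.0102 in inhibitory neuron-like cells. Of 13 glutamate receptor genes, 9 were highest in the oligodendrocyte lineage, 2 in astrocyte-like and 2 in excitatory neuron-like cells. The AMPA receptor subunit Gria3 (chromosome X, 41400854 to 41678601, plus strand) was at 2.02 in the oligodendrocyte lineage (1.497 to 2.38), against 0.215 in excitatory neuron-like cells, and Grm3 (chromosome 5, 9485541 to 9725170, minus strand) was at 2.84 in astrocyte-like cells (2.31 to 3.34). Each of these 5 genes was highest in that class among the 9 classes given per library in 6 of 6 libraries.

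**Figure D2:**
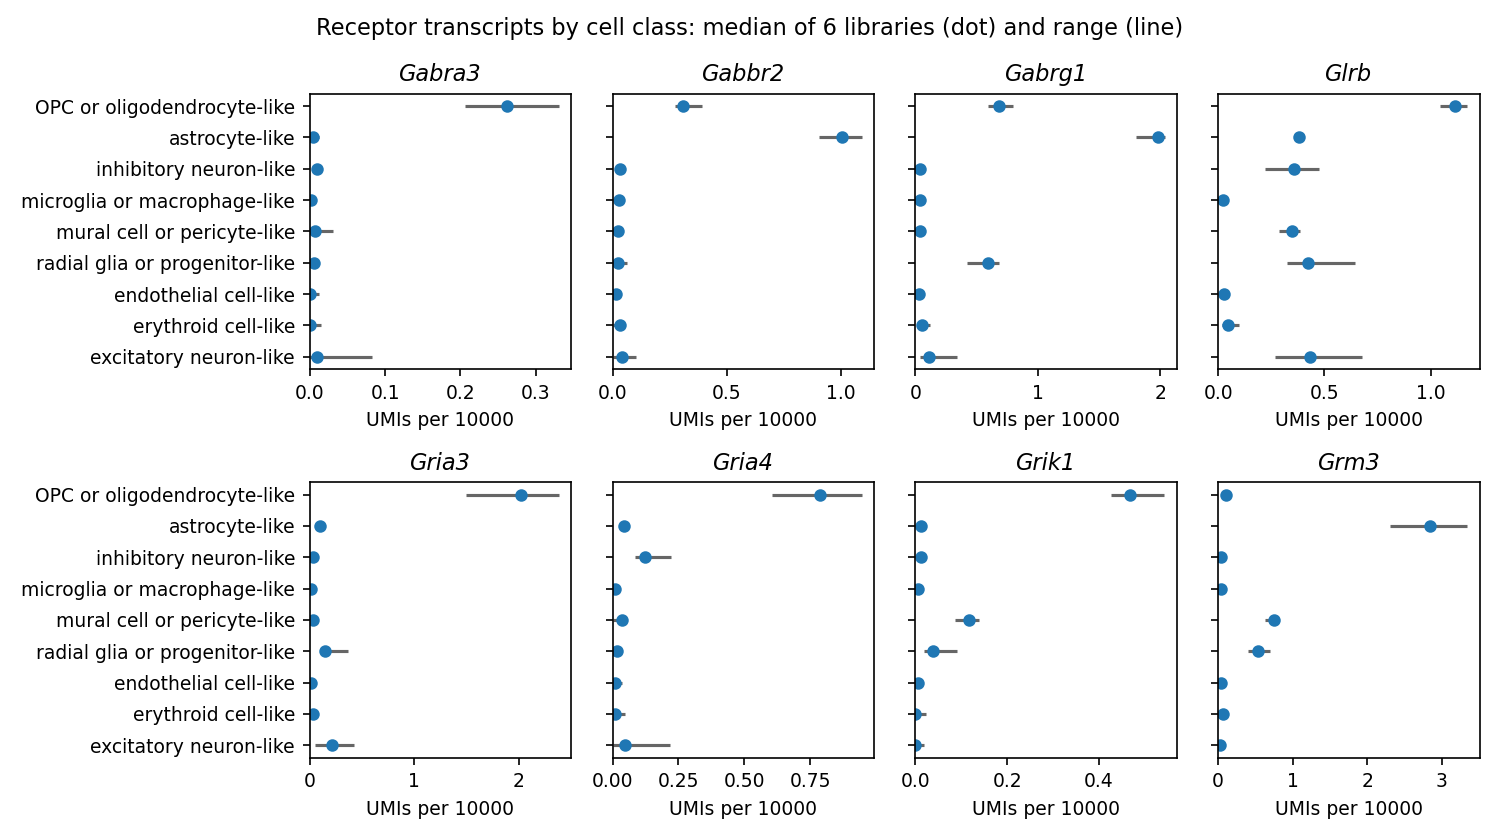
Mean UMIs per 10000 of 4 GABA or glycine receptor genes (top) and 4 glutamate receptor genes (bottom) in 9 cell classes (OPC, oligodendrocyte precursor cell). Dots are medians of 6 libraries and lines their range, and Gria3 reached 2.02 in the oligodendrocyte lineage and Grm3 2.84 in astrocyte-like cells.

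Of 14 potassium channel genes, 6 were highest in the oligodendrocyte lineage, where Kcnd2 was at 1.73 UMIs per 10000 (1.59 to 1.85) and Kcna1 at 0.291 (0.255 to 0.342). Most synaptic genes were highest in neuronal classes or the oligodendrocyte lineage. Of 18 presynaptic release genes, 9 were highest in excitatory neuron-like cells, 4 in the oligodendrocyte lineage and 3 in inhibitory neuron-like cells. Cplx2, a regulator of vesicle fusion, was at 3.06 in excitatory neuron-like cells (2.68 to 3.37), and Nrxn3 at 6.73 in inhibitory neuron-like cells (6.24 to 7.01). Of 14 postsynaptic density genes, 7 were highest in the oligodendrocyte lineage, among them Lrrtm2 at 0.828 (0.634 to 0.942). Stx1a at 0.520 (0.401 to 0.603) and Baiap2 at 1.23 (1.05 to 1.30) were highest in endothelial-like cells. Axon growth and cytoskeleton genes were highest in inhibitory neuron-like cells for 12 of 18, with Map1b at 19.6 (17.4 to 21.2). Of 11 neurotrophin and plasticity genes, 3 each were highest in astrocyte-like and excitatory neuron-like cells. The receptor gene Ntrk2 was at 19.4 in radial glia-like cells (19.1 to 20.7), and Bdnf, a neurotrophin, at 0.200 in astrocyte-like cells (0.178 to 0.232). Of 22 tau and amyloid processing genes, 6 were highest in excitatory neuron-like cells and 5 in endothelial-like cells. The lipid carrier Apoe was at 337 UMIs per 10000 in astrocyte-like cells (307 to 355) and 157 in radial glia-like cells.

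Immediate early genes were highest mainly in endothelial-like cells in libraries 1 to 3 but not in libraries 4 to 6, and other stress lists were divided among classes. Of the immediate early genes at the floor, 9 of 13, 10 of 13, 10 of 13, 4 of 11, 4 of 12 and 3 of 11 were highest in endothelial-like cells in libraries 1 to 6. In these cells Dusp1, a phosphatase induced by stress, was at 15.9, 15.2, 15.6, 1.67, 1.69 and 2.06 UMIs per 10000, and Klf4 at 3.91, 4.73, 4.20, 1.55, 1.10 and 1.32, so no median of the 6 is given for them. Dusp1 and Klf4 were still highest in endothelial-like cells in 6 of 6 libraries. Of 22 apoptosis and p53 genes, 7 were highest in endothelial-like cells, including the cell cycle inhibitor Cdkn1a at 5.43 (4.02 to 6.32), and 4 each in mural-like and excitatory neuron-like cells. In 6 of 6 libraries this held for 3 of the 7 endothelial, 2 of the 4 mural and 0 of the 4 excitatory genes. Of 18 genes of endoplasmic reticulum and integrated stress, 5 were highest in microglia-like cells, with the chaperone gene Hsp90b1 at 9.02 (8.05 to 10.3), and 4 in radial glia-like cells, with Phgdh at 12.9 (12.1 to 13.6). Of 14 heat shock genes, 4 were highest in excitatory neuron-like cells, 1 of them in 6 of 6 libraries, and Hspa1a was at 1.66 in microglia-like cells (0.784 to 2.54). Of 17 antioxidant genes, 5 were highest in radial glia-like cells and 3 in astrocyte-like cells, where the cystine transporter Slc7a11 was at 2.46 (2.37 to 2.82).

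Inflammatory genes were highest in microglia-like cells for 7 of 10, with the chemokines Ccl3 at 2.47 UMIs per 10000 (2.02 to 3.31) and Ccl4 at 1.86 (0.973 to 3.69). Of 14 interferon response genes, 5 were highest in endothelial-like and 4 in mural-like cells, where Ifitm3 was at 12.05 (10.2 to 13.5). Autophagy and lysosome genes were highest in microglia-like cells for 6 of 20, with the cathepsin genes Ctsb at 53.4 (44.2 to 62.9) and Ctsd at 53.3 (43.0 to 66.0). Of 12 iron handling genes, 6 were highest in endothelial-like cells, with the transferrin receptor Tfrc at 9.07 (5.67 to 12.9) and the iron exporter Slc40a1 at 7.55 (6.84 to 8.08). Over all cells Tfrc was at 0.711, 0.943, 0.585, 0.434, 0.465 and 0.463 in libraries 1 to 6. From the list of blood and serum genes, 6 of 8 are erythroid markers, and the other gene at the floor, the anion exchanger Slc4a1, was at 0.423 in erythroid-like cells (0.219 to 0.573).

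Metabolic lists differed by class as well. Sterol synthesis genes were highest in astrocyte-like cells for 16 of 17, among them Msmo1 at 14.9 UMIs per 10000 (13.2 to 16.5). Nuclear oxidative phosphorylation genes were highest in mural-like cells for 19 of 38, with Atp5b at 15.3 (15.01 to 17.5). Of 22 glycolysis and hypoxia genes, 6 were highest in mural-like cells and 5 each in astrocyte-like and endothelial-like cells. The glucose transporter Slc2a1 was at 8.10 in endothelial-like cells (7.39 to 8.90) and Vegfa at 1.37 in astrocyte-like cells (1.03 to 1.52). Ribosomal protein genes were highest in microglia-like cells for 45 of 52, and Rps29 was at 57.5 there (54.3 to 69.3). Among the named classes, S phase genes were highest in inhibitory neuron-like cells for 11 of 20 and in microglia-like cells for 9, and G2 and M phase genes in inhibitory neuron-like cells for 12 of 15. The 1495 dividing cells left unnamed, more than the 1123 of the inhibitory class or the 480 of the microglia class, were not ranked. Without the dividing clusters, 6 of 19 S phase genes were highest in inhibitory neuron-like and 13 in microglia-like cells, and of 11 G2 and M phase genes 0 and 8 were. Over all cells of the class, Rrm2, a subunit of ribonucleotide reductase, was at 3.82 in inhibitory neuron-like cells (3.44 to 4.57).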

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

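Library 1 stood apart from the other 5 in its oligodendrocyte-lineage cells, which were 26.1% of its cells against 23.4% in the next library. It also stood apart in the summed S phase genes, at 12.5 UMIs per 10000 against 11.1 in the next library. These were 2 of the 40 results examined for an outlying library, and chance alone gives about 1 in 20.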

How the results depend on the processing

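No paired analysis was possible because the cell columns carry no sample or replicate number of the labels. For the same reason the other settings chosen for the tests of sevoflurane against control were not run. Of 144 values of class shares under other settings, 135 moved by less than 1 SD over the libraries, including all that left out 1 library. Leaving out 1 of 6 libraries cannot move a median by more than 1 SD, so those values are no check of it. As a share of the 3 neuronal classes only, inhibitory neuron-like cells, their dividing cluster included, were 91.7%, excitatory neuron-like 5.21% and Cajal-Retzius-like cells 2.62%, by the smaller denominator. Clustering with the list genes gave 25.4% astrocyte-like cells and 5.98% unnamed, and no radial glia-like cells, and resolution 2 gave no radial glia-like cells either. Unnamed cells were 5.28% at resolution 0.5, 9.47% at resolution 2 and 7.40% without called doublets. With at least 1000 detected genes required, erythroid-like cells fell to 0.383%, since most of them hold fewer genes. The cause of the other shifts was not tested. Of 279 values of genes within classes, 262 moved by less than 1 SD, and of 144 ratios between libraries for gene lists, 130 did. In none of 10 settings did a library change its 2 nearest libraries, though thinning the cells leaves the expected means as they are. The 3 classes with under 50 cells in some library have no gene levels per library.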

Other observations

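All tests in this part were chosen after the results were seen. Some genes differed widely between the 6 libraries. Of 9378 genes, 93 had a highest library at least 2 times the lowest. In UMIs per 10000 for libraries 1 to 6, the early response gene Egr1 was at 1.18, 0.914, 0.955, 0.271, 0.213 and 0.290, and Dusp1 at 1.54, 1.63, 1.56, 0.459, 0.476 and 0.568. The linker histone gene Hist1h1e was at 1.89, 1.61, 1.497, 0.372, 0.375 and 0.388. Klf2, a flow-responsive regulator highest in endothelial-like cells, was at 1.55, 1.93, 1.39, 0.699, 0.535 and 0.659. Spp1, highest in microglia-like cells, was at 0.583, 0.958, 1.35, 2.63, 2.76 and 3.39, and Insm1 at 0.298, 0.544, 0.867, 0.792, 1.15 and 1.19. The pericyte channel subunit Abcc9 was at 0.624, 0.630, 0.412, 0.263, 0.207 and 0.289. These means over all cells move with class shares too: mural-like cells were 7.24%, 7.35%, 5.79%, 4.39%, 3.41% and 5.21% of libraries 1 to 6, and within them Abcc9 lay between 5.27 and 8.29.

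The summed immediate early genes were at 11.4, 10.9, 10.9, 5.96, 5.94 and 6.70 UMIs per 10000 in libraries 1 to 6. Within endothelial-like cells the sum without marker genes was 45.9, 45.6, 45.9, 11.3, 10.6 and 11.8, and within inhibitory neuron-like cells 7.85, 6.67, 7.59, 4.39, 4.47 and 4.23. For other lists the ratio of the highest to the lowest library was 1.66 for blood and serum genes, 1.36 for G2 and M phase, 1.35 for tau and amyloid processing, 1.24 for interferon response, 1.21 for glutamate receptors, 1.10 for GABA and glycine receptors, 1.03 for presynaptic release and 1.03 for apoptosis and p53.

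The libraries fell into 2 clusters of 3, and on the first principal component, with 67.3% of the variance between libraries, libraries 1 to 6 lay at -13.3, -12.3, -9.84, 12.4, 11.0 and 12.1. A difference in the shares of cell classes is argued against as the whole source, because in 7 of 9 classes all 6 libraries had the same 2 nearest libraries as over all cells, all but the erythroid-like and the excitatory neuron-like. Unequal depth is argued against too, since the median UMIs per cell were 5733, 5488.5, 5808, 6001, 5434 and 5751, and 0 of 6 libraries had the same 2 nearest libraries in this depth as in gene levels, over all cells and in each class but the excitatory neuron-like, with 3 of 6. Exposure and a batch of culture, dissociation or sequencing stay open and untested, because no label ties a library to either. The descriptions number the 3 controls 1 to 3 and the exposed samples 4 to 6, but nothing says that these are the library numbers, so the clusters were given no exposure.

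Most cells of these samples labelled as neurons carried no neuronal class. The summed astrocyte markers were 37.5 times as high in astrocyte-like as in erythroid-like cells (22.4 to 46.7), at median depths of 6688 and 7674 UMIs. The astrocyte class was named from these markers, so a high ratio was partly built in and cannot decide on free glial RNA. Erythroid-like cells held 3.45 UMIs per 10000 of these markers, which shows the free astrocyte RNA in those cells only. Hbb-bs had a UMI in 93.3%, 92.6%, 91.5%, 91.8%, 84.1% and 91.0% of the cells of libraries 1 to 6, while erythroid-like cells were 3.42%. Haemoglobin RNA was thus found in most cells outside that class, and low levels of a gene in a class may come from free RNA. Missed neurons are argued against, since 22.5% of cells held 20 or more UMIs of pan-neuronal genes per 10000. The highest counts of detected genes in libraries 1 to 6 were 5133, 5119, 5117, 5132, 5125 and 5114, and the lowest lay between 201 and 203. Ends this close together point to limits on detected genes, though no filter is stated. Whether an upper limit removed large neurons cannot be told apart from their absence, because removed cells leave no value. Of the Cajal-Retzius-like cells, 47.8% held at least 4500 genes, near the highest count of 5133. That share was 1.41% (0.709% to 1.83%) over the 3 neuronal classes and 2.70% over all cells, but these are cells that stayed below any such limit. Erythroid, endothelial and mural-like cells together were 13.1% of a library (10.2% to 16.2%), and where the non-neuronal cells came from was not tested.

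Ttr, the transthyretin gene on chromosome 18 (20665280 to 20674321), had 7, 8, 4, 4404, 2 and 7732 UMIs in libraries 1 to 6, and 5 cells held 96.0% of those in library 4 and 96.3% in library 6. S100a8 had 942, 1886, 661, 17, 478 and 7 UMIs, and 5 cells held 98.5%, 98.7%, 99.1% and 97.7% of those in libraries 1, 2, 3 and 5. Of the UMIs of 3 beta globin genes, 85.7% came from Hbb-bs and 14.3% from Hbb-bt, while the embryonic gene Hbb-y gave 19 of 4318792. Xist, the RNA of the inactive X chromosome, had a UMI in 95.7%, 93.9%, 90.1%, 92.1%, 94.2% and 92.0% of the cells of libraries 1 to 6. In erythroid-like cells the share was 21.2% (15.4% to 31.6%) at a median depth of 7674 UMIs and a median of 295 detected genes. Haemoglobin transcripts such as Hbb-bs left few UMIs for other genes in these cells, but the cause of the lower share was not tested. In inhibitory neuron-like cells the share was 98.5% (98.1% to 98.8%) at 3702 UMIs.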
